A study of Bos taurus with 16 samples.

How the data were processed

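Gene expression was measured in day 6 bovine blastocysts that had been cultured with 0.5 mM L-carnitine or without it, separately for the Jersey and the Holstein breed. L-carnitine carries long-chain fatty acids into mitochondria, where they are oxidised. Per the labels, total RNA was amplified in a pair of T7 polymerase rounds, labelled with Cy3 or Cy5 and hybridised to a bovine embryo array with both colours on each array. Each of the 16 arrays held carnitine RNA in one dye and control RNA of the same breed in the other. The series title calls the embryos in vivo, while the protocols describe in vitro maturation, fertilisation and culture. The protocols are followed here for what the embryos were, and the title's wording stays unexplained.

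The deposited scanner files give the intensity of each spot and its local background for both dyes, as mean and median over the spot's pixels, with background not subtracted. The deposited series table holds a log2 ratio per probe and array, made by the authors with a normalization that the sources used here do not state. Its direction was settled from the values. It correlated positively with the scanner's log2(Cy5/Cy3) where carnitine RNA was in Cy5, with r from 0.758 to 0.973, and negatively where control RNA was in Cy5, with r from -0.994 to -0.681, so each column runs as carnitine over control. Column medians lay near 0. For the Jersey arrays with carnitine in Cy5, replicates 1 to 4, they were -0.016, -0.011, 0.0051 and -0.0067. With control in Cy5 they were 0.00093, 0.0072, 0.011 and -0.0022. For the Holstein arrays with carnitine in Cy5 they were -0.023, -0.00056, -0.011 and -0.014, and with control in Cy5 0.0010, 0.020, 0.0079 and -5.8e-05. How the authors centred and scaled the columns stays unknown. The deposited column of the Holstein array of replicate 1 with carnitine in Cy5 correlated with the values made here with r of 0.652, against at least 0.914 for the other 15 arrays.

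The scanner's mean foreground was corrected for local background by normexp with an offset of 50, and log ratios were fitted by loess within each array, with control spots at weight 0. No scaling between arrays was applied. Spots of one probe were averaged, and each array's log2(Cy5/Cy3) was turned to carnitine over control by the dyes in the labels. The series states 4 replicates per breed with dye swaps but does not list the pairs. The 2 arrays of one breed with opposite dyes and the same area number on their slides were taken as a dye-swap pair and averaged, which left 4 replicates per breed, 8 in all. This pairing was checked on deviations from the breed-by-orientation means. The pairs correlated with r from 0.699 to 0.955 in Jersey and from 0.707 to 0.950 in Holstein. In each breed the area pairing had the highest mean r of the 24 possible pairings (exact one-sided p = 0.0417). The other pairing considered for Holstein, within slides, had a mean r of 0.032. In Jersey each slide held a single dye orientation, while each Holstein slide held both. A dye bias that differs between slides therefore cancels in the Holstein mean. It stays in the Jersey mean and in the difference between breeds, where it cannot be told apart from carnitine.

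A probe was tested if its foreground passed the array's mean plus 2 SD of the 153 negative-control spots in at least 6 of the 8 array channels of at least one of the 4 RNA groups, which are breed by treatment. Of 43794 probes, 27303 passed. The platform annotation names 1 gene for 21790 probes, several for 0 and none for 22004. Symbols were brought up to date through the RefSeq gene table of assembly ARS-UCD2.0, where 20068 probes had a current symbol, 1644 an older one that was replaced, and 78 kept the name in the file. The genome build behind the array's design is not named, so no coordinates are given. The tested probes covered 11096 named genes. For a gene with several tested probes, a gene named by its rank has the values of its probe with the smallest p. The genes nearest to the treatment and the members of gene lists have those of the probe with the highest mean intensity.

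Tests were run with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading files, and figures were drawn with matplotlib 3.10.9. One linear model with 1 coefficient per breed was fitted to the 8 replicate values, so both breeds share an estimate of the spread per probe. The carnitine effect was tested in Jersey, in Holstein, as the mean of both, and as the difference, Jersey minus Holstein. P-values were moderated by eBayes and adjusted by the Benjamini-Hochberg method over all 27303 probes, with a threshold of 0.05. All tests are two-sided unless said otherwise. P-values measure spread between these replicates, each a pool of embryos, and the number of replicates, 4 per breed, limits the precision. Values are given as mean ± SD of the log2 ratio of carnitine over control, so that positive values are higher with carnitine.

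The samples, comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Of the 26 gene lists fixed, 24 had at least 5 measured genes and were tested. No gene of the mitochondrial genome list was measured, and the sex-linked list had 4 measured genes, whose values are given without a list test. Lists were tested by limma's camera with a preset correlation of 0.01 between genes, beside camera with an estimated correlation and limma's fry. Named genes are, per comparison and direction, the called probes of one sign in all replicates, by size of change. Where fewer than 5 pass, as here in every comparison, those with the smallest unadjusted p up to 5 are named as not passing. Each list adds up to 4 members with the smallest unadjusted p. Named in any case are 11 genes nearest to the treatment, from CPT1A to PRKAA1. One of these, PPARA, is on the array but did not pass the filter on dim probes. Uncharacterised symbols are skipped.

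The test was tried on simulated data with this layout and 27303 probes before use. For the Jersey effect it recovered 40.3% of probes changed 1.5-fold, 52.2% of those changed 2-fold and 81.8% of those changed 4-fold, with 6 false calls. For the Holstein effect it recovered 38.8%, 61.2% and 92.4%, with 12 false calls. The simulated noise was normal and drawn independently for each probe, at the SD measured for that probe. Each measured SD rests on 8 replicates and was taken as the true one. Those too low by chance would make a change easier to recover. Real probes can also move together across replicates. For both reasons these rates may not hold for the data, and the recovery may be overstated.

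Alternatives changed one choice at a time, except that each fit to all 16 arrays replaced the pair means by single arrays with a dye term per breed, and some of these fits added a block or a slide term. The alternatives were the background correction, the normalization within and between arrays, the filter on dim probes, the variance prior, the threshold, the deposited values, the pairing, the treatment of all 16 arrays with or without a replicate block, the slide, each breed fitted alone, the probe per gene, the set test, and leaving out each replicate. Median foreground, a limit from the negative controls' median and MAD, a sex index as covariate, Holstein replicate 1 from a single array, each Holstein slide alone, and the Holstein slide as a fixed term with the replicate block were added after seeing the data. The sex index is the log2 ratio of XIST minus the mean of those of DDX3Y and EIF1AY. A probe below the negative-control limit on every array of one group has only a bound there. It was computed per channel after loess and Aquantile from the dimmest probe above the limit on each array.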

Results

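Day 6 blastocysts of 2 cattle breeds, Jersey and Holstein, were profiled after culture with or without 0.5 mM L-carnitine, a nutrient that carries fatty acids into mitochondria. Each breed had 8 arrays, which formed 4 replicates of 2 dye-swapped arrays each, and every array set carnitine RNA directly against control RNA of its breed. Median spot intensity per array ran from 195 to 352 in Cy3 and from 125 to 301 in Cy5, over median local backgrounds of 24 to 32 and 28 to 43. The share of probes above the negative-control limit ran from 18.4% to 76.0% in Cy3 and from 33.5% to 68.9% in Cy5. The lowest Cy3 share belonged to the Holstein array of replicate 3 with carnitine in Cy5, whose limit was 736 against a median of 222. The deposited values of the Holstein array of replicate 1 with carnitine in Cy5 had r of 0.652 with those made here, against at least 0.914 for the others. The SD between the 2 arrays of a pair, with the dye effect removed, was 0.13 on the log2 scale, and that between replicates of a breed was 0.43. Replicates of one breed did not share a profile across probes, with r from -0.35 to 0.30 between Jersey replicates and from -0.29 to 0.31 between Holstein replicates. Probes are not independent replicates.

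The sex-linked transcripts differed between the carnitine and the control pool of single replicates. XIST, the RNA that silences an X chromosome in female cells, had log2 ratios of 0.41, -0.72, 0.08 and 1.19 in Jersey replicates 1 to 4 and of 0.19, -0.89, 0.66 and -0.94 in Holstein replicates 1 to 4. The Y-linked DDX3Y had ratios of 0.0046, 0.63, 0.16 and -0.13 in Jersey and of -0.23, 0.27, 0.14 and 0.77 in Holstein. The Y-linked EIF1AY had -0.41, 0.67, -0.31 and -0.07 in Jersey and -0.24, 0.83, -0.06 and 0.49 in Holstein. In Jersey replicate 2 and Holstein replicates 2 and 4, XIST was lower and both Y-linked genes were higher in the carnitine pool. SRY, the testis-determining gene, averaged -0.0041 ± 0.04 in Jersey and 0.05 ± 0.05 in Holstein (SD, n = 4).

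In Jersey blastocysts the measured genes named beforehand as nearest to the treatment varied between replicates by more than their mean change. CPT1A, which attaches fatty acids to carnitine at the outer mitochondrial membrane, had a log2 ratio of 0.12 ± 0.15 (SD, n = 4), and its muscle-type form CPT1B had -0.11 ± 0.34. The carnitine importer SLC22A5 had -0.33 ± 0.44, the mitochondrial carnitine carrier SLC25A20 had -0.12 ± 0.46, CPT2 on the inner membrane had -0.14 ± 0.42, and carnitine acetyltransferase CRAT had -0.24 ± 0.61 (SD, n = 4). PLIN2, which coats lipid droplets, had 0.30 ± 0.64, and the triglyceride lipase PNPLA2 had -0.17 ± 0.78 (SD, n = 4). PPARGC1A, a regulator of mitochondrial biogenesis, had 0.01 ± 0.07, and the AMP-activated kinase subunit PRKAA1 had -0.07 ± 0.54 (SD, n = 4). Another gene of the carnitine list, ALDH9A1, an enzyme of carnitine synthesis, had 1.98, -0.40, 2.42 and 2.12 in replicates 1 to 4. The other PRKAA1 probes had -0.15 and -0.25 in Jersey. The ribosomal proteins, of which 51 of 64 measured genes had negative ratios, passed by camera with a preset correlation and not with an estimated one.

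No single probe passed in Jersey. With limma, 0 of 27303 probes reached an adjusted p of 0.05, and the smallest adjusted p was 0.9999. At unadjusted p under 0.05 there were 763 probes, 415 up and 348 down, where chance alone gives 1365. The highest-ranked genes are therefore named as not passing. POFUT2, which fucosylates secreted proteins, had 0.51 ± 0.14, the Hedgehog receptor PTCH1 had 0.52 ± 0.26, and TNRC6A, part of the microRNA silencing machinery, had 0.47 ± 0.22 (SD, n = 4). DFFB, a DNase of apoptosis, had 0.29 ± 0.07, and SCFD1, which acts in transport from the endoplasmic reticulum to the Golgi, had 0.42 ± 0.18 (SD, n = 4). On the other side stood MRPS11, a mitochondrial ribosomal protein, at -0.48 ± 0.16, the bicarbonate transporter SLC4A7 at -0.34 ± 0.18, DAPL1 at -0.72 ± 0.30, the endosomal trafficking protein MON1B at -0.52 ± 0.35, and METTL26 at -0.40 ± 0.16 (SD, n = 4). All of these 10 genes had one sign in all 4 Jersey replicates, as the rule by p favours. A dye bias that differs between the Jersey slides would be shared by all 4. POFUT2 was above the negative-control limit on 6 of 8 arrays in the carnitine channel and on 1 of 8 in the control channel, and TNRC6A on 8 and 2 of 8. The other 3 probes of MRPS11 had -0.22, -0.46 and -0.37, and the other 5 of METTL26 ran from -0.39 to -0.18. The other probes of TNRC6A, at -0.0032, of PTCH1, at -0.01 and 0.03, of SLC4A7, at 0.05 and 0.03, and of MON1B, at -0.06 and 0.20, did not show the ratio of the named probe.

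The ribosomal protein list was lower with carnitine in Jersey by camera with the preset correlation, with a median log2 ratio of -0.09 over 64 genes and an adjusted p of 3.53e-05. With an estimated correlation the p was 0.141, or 0.996 after adjustment, and fry gave p = 0.210, so the call held only with the preset correlation. Examples are RPS14 at -0.30 ± 0.25, RPS19 at -0.55 ± 0.46, RPL15 at -0.31 ± 0.08 and RPL29 at -0.29 ± 0.21 (SD, n = 4). None of the 64 passed over all probes in limma, or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The call was also lost when median centring took the place of loess, with an adjusted p of 0.780 by limma's camera. The list's replicate medians were -0.12, -0.0039, -0.05 and -0.09 in Jersey replicates 1 to 4, and -0.27, 0.12, -0.02 and -0.03 in Holstein. On single arrays of Jersey the list median was above 0 on all 4 arrays with carnitine in Cy5, from 0.03 to 0.07, and below 0 on all 4 with control in Cy5, from -0.26 to -0.06.

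The remaining 23 lists did not pass in Jersey, with adjusted p from 0.544 upwards by camera and 0 members passing in limma, over all probes or adjusted over the list alone. Fatty acid oxidation enzymes had a median of 0.03, with 16 of 26 positive, and the 2 members ranked first, ACAT1 and HADH, had 0.40 ± 0.42 and 0.26 ± 0.36 (SD, n = 4). In the carnitine shuttle, 8 of 16 were positive, and ALDH9A1 had 1.53 ± 1.30 (SD, n = 4). In triglyceride synthesis, where 14 of 29 were positive, DGAT2 had 0.68 ± 0.37 and DGAT1 had -0.19 ± 0.17 (SD, n = 4), both catalysing its last step. Cholesterol synthesis had a median of -0.10, with 15 of 22 negative, and squalene synthase FDFT1 had -0.39 ± 0.57 (SD, n = 4). Without Jersey replicate 2 the cholesterol list was called as well, with an adjusted p of 0.00214 at the preset correlation and of 0.720 at an estimated one by limma's camera. Histone and DNA methylation genes were positive in 22 of 34, with an adjusted p of 0.544 by limma's camera, and the histone methyltransferase SETDB1 had 0.37 ± 0.24 (SD, n = 4). Glycolysis was negative in 12 of 22, with TPI1 at -1.22 ± 1.31, and the cell cycle in 23 of 41, with cyclin CCNE2 at 0.45 ± 0.29 and CCND3 at -0.32 ± 0.18 (SD, n = 4). Among markers of the blastocyst's lineages, IFNT, the interferon secreted by the trophectoderm, had 1.13 ± 1.04, the inner cell mass gene DPPA2 had -0.35 ± 0.38 and the hypoblast gene CTSV had -0.23 ± 0.17 (SD, n = 4). Positive members numbered 11 of 26 for the trophectoderm, 13 of 19 for the inner cell mass and 10 of 17 for the hypoblast.

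Other Jersey lists stood as follows. Lipid droplet genes were positive in 7 of 16, with ABHD5, an activator of lipolysis, at 0.31 ± 0.54, and fatty acid uptake genes in 9 of 16, with SLC27A1 at 0.23 ± 0.11 (SD, n = 4). AMPK, PPAR and mitochondrial biogenesis genes were positive in 19 of 29, with the mitochondrial transcription factor TFAM at 0.13 ± 0.17, and nuclear oxidative phosphorylation genes in 35 of 77, with the complex I subunit NDUFS7 at -0.28 ± 0.14 (SD, n = 4). The TCA cycle had 14 of 23 positive with IDH3B at -0.19 ± 0.16, antioxidant genes 24 of 39 with the glutathione peroxidase GPX4 at -0.30 ± 0.18, apoptosis 8 of 20 with BCL2L1 at -0.18 ± 0.08, and stress response 19 of 38 with the chaperone CANX at 0.29 ± 0.31 (SD, n = 4). Junction and blastocoel genes had 16 of 29 positive with connexin GJA1 at -0.51 ± 0.54, maternal oocyte transcripts 7 of 17 with OOEP at 0.18 ± 0.08, interferon response 5 of 13 with ISG15 at -0.28 ± 0.46, cumulus cell markers 6 of 12 with COL1A2 at -0.44 ± 0.33, and sperm markers 4 of 9 with LDHC at 0.12 ± 0.14 (SD, n = 4). Median, mean and test differed in sign for the carnitine shuttle, lipid droplet, triglyceride synthesis, junction and cumulus lists.

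In Holstein blastocysts the means of the same genes were again smaller than their SD over replicates, with 1 exception. CPT1A had -0.07 ± 0.24, CPT1B -0.04 ± 0.14, CPT2 -0.11 ± 0.24, SLC25A20 -0.21 ± 0.37, SLC22A5 0.02 ± 0.48 and CRAT 0.20 ± 0.85 (SD, n = 4). PLIN2 had 0.45 ± 1.06, PNPLA2 0.21 ± 0.78, PPARGC1A -0.06 ± 0.08 and PRKAA1 -0.31 ± 0.24 (SD, n = 4). Of these, PRKAA1 alone had a mean larger than its SD, and it was negative in 4 of 4 replicates, but the other PRKAA1 probes had 0.01 and 0.20. The highest-ranked genes included SLC27A4, a fatty acid transporter, and SEC61A1, the pore of the endoplasmic reticulum's protein channel, neither of which passed over all probes.

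**Figure D1:**
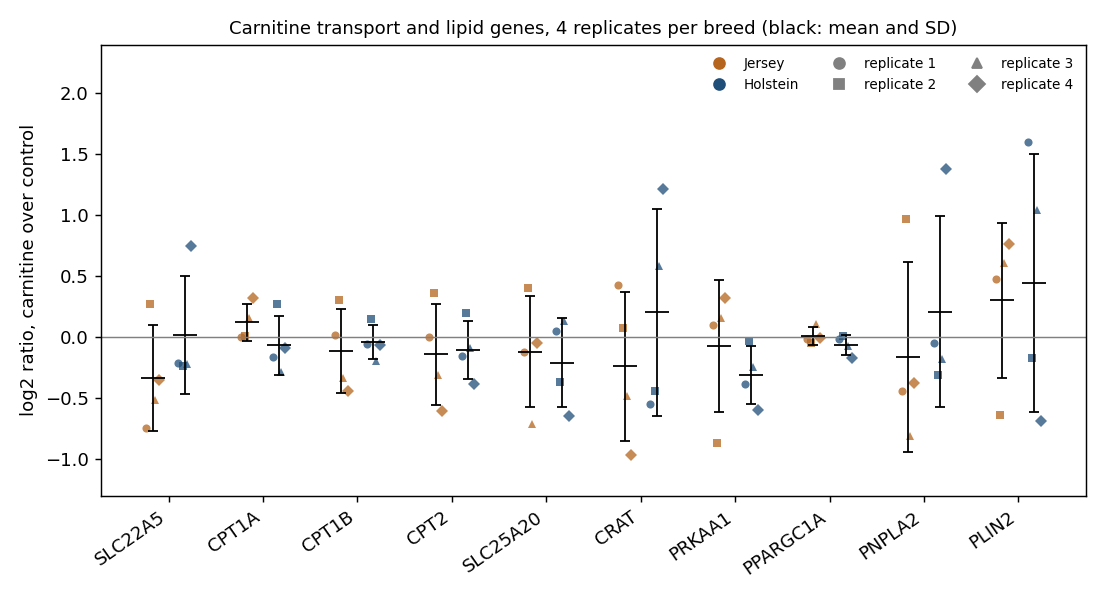
Log2 ratio of carnitine over control (vertical axis) for the 10 measured genes nearest to the treatment (horizontal axis), in Jersey (orange) and Holstein (blue). Symbols are replicates, and black bars are the mean and SD of 4 replicates. Replicates fall on both sides of 0 for most genes, as for PLIN2 in Holstein, from -0.69 to 1.60.

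With limma, 0 of 27303 probes passed in Holstein, where the smallest adjusted p was 0.381. At unadjusted p under 0.05 there were 1579 probes, against 1365 by chance, with 1020 up and 559 down. Among the highest-ranked, not passing, UBE2G1, a ubiquitin-conjugating enzyme, had 0.48 ± 0.06, the kinase PIM1 had 1.21 ± 0.42, SLC27A4 had 0.71 ± 0.23 and SEC61A1 had 1.22 ± 0.59 (SD, n = 4). DHX34, an RNA helicase of nonsense-mediated decay, was above the negative-control limit on 7 of 8 arrays in the carnitine channel and on 0 of 8 in the control channel. The lower bound on its mean ratio was 1.30-fold, given without an error, and its adjusted p by limma was 0.705. On the other side stood the histone methyltransferase NSD3 at -0.42 ± 0.05, the cyclin-dependent kinase subunit CKS1B at -0.35 ± 0.06, the replication fork protein TIMELESS at -0.40 ± 0.12, PGS1 of cardiolipin synthesis at -0.50 ± 0.23, and SETD3, an actin methyltransferase, at -0.36 ± 0.12 (SD, n = 4). NSD3 was above the limit on 4 of 8 arrays in the carnitine channel and 7 of 8 in the control channel, and SETD3 on 3 and 7 of 8. The second NSD3 probe had -0.33 and the second SETD3 probe -0.11. The other PGS1 probes, at 0.11 and 0.78, ran against the named one, and the other UBE2G1 probes had 0.00062 and 0.18.

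Leaving out single replicates changed the Holstein count. Without replicate 3 limma called 13 probes, all higher with carnitine, among them SEC61A1 with an adjusted p of 0.00288. Without replicate 2 it called 1, ZNF24, with a log2 ratio of -1.52. Both names were chosen after their values were seen. Taking all 16 arrays with the replicate as a block gave 2 calls, and adding slide as a fixed term to that fit also gave 2. Each Holstein slide alone gave 0.

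No list passed in Holstein by camera, although 3 came near. Cholesterol synthesis genes were negative in 17 of 22, with a median of -0.32 and an adjusted p of 0.0673, and cumulus cell markers were negative in 9 of 12, with a median of -0.13 and an adjusted p of 0.0673. Lipid droplet genes were positive in 12 of 16, with a median of 0.07 and an adjusted p of 0.0785. With an estimated correlation the adjusted p was 0.737, 0.604 and 0.604. In the cholesterol pathway FDFT1 had -0.85 ± 0.49 and FDPS, which makes its substrate, had -0.66 ± 0.75, while the later enzyme DHCR7 had 0.78 ± 0.89 and MVD had 0.41 ± 0.37 (SD, n = 4). Among cumulus markers, aromatase CYP19A1 had -0.50 ± 0.53, INHBA -0.70 ± 0.83, LUM -1.29 ± 1.26 and STAR -0.59 ± 0.65 (SD, n = 4). LUM was above the negative-control limit on 2 of 8 Holstein arrays in the carnitine channel and 7 of 8 in the control channel. Among lipid droplet genes, HILPDA had 0.45 ± 0.26 and PLIN3 had 1.05 ± 0.91 (SD, n = 4). The cholesterol list's replicate medians swung from -0.99 in Holstein replicate 2 to 0.45 in replicate 4, and without replicate 4 the list was called with an adjusted p of 1.27e-06 at the preset correlation and had 0.537 at an estimated one. Without replicate 2, ribosomal proteins and cell cycle genes were called as lower in Holstein, each with an adjusted p of 0.0104 by limma's camera at the preset correlation. At an estimated correlation it was 0.841 and 0.627. SLC27A4, of the fatty acid uptake list, passed when adjusted over the list alone, 1 of 16 genes, and not over all probes. In the other 23 lists 0 members passed in limma either way.

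The remaining Holstein lists gave adjusted p from 0.298 upwards. Apoptosis genes were positive in 13 of 20, with the pore-forming BOK at 1.04 ± 0.81, DIABLO at 0.30 ± 0.14 and FADD at 0.75 ± 0.67 (SD, n = 4). The carnitine shuttle was negative in 13 of 16, with ACSL6 at -0.26 ± 0.24, and fatty acid oxidation in 15 of 26, with HADH at -0.32 ± 0.18 (SD, n = 4). Triglyceride synthesis was negative in 16 of 29, with AGPAT1 at -0.27 ± 0.08 and the desaturase SCD at -0.88 ± 0.95 (SD, n = 4). Nuclear oxidative phosphorylation genes split into 38 positive and 39 negative, with COX4I1 at -0.47 ± 0.27 and ATP5PF at -0.69 ± 0.59 against NDUFA10 at 0.54 ± 0.35 (SD, n = 4). For trophectoderm markers, 12 of 26 were positive, with the transcription factor TEAD4 at 0.64 ± 0.43, IFNT at 1.51 ± 1.37, GATA3 at -0.41 ± 0.37 and keratin KRT19 at -1.51 ± 1.15 (SD, n = 4). Inner cell mass markers were positive in 12 of 19, with SOX2 at 0.60 ± 0.71, and hypoblast markers in 11 of 17, with COL4A1 at 0.51 ± 0.56 (SD, n = 4). Glycolysis was negative in 13 of 22, with ENO1 at -0.46 ± 0.31, the TCA cycle in 14 of 23, with IDH3B at -0.33 ± 0.28, and the cell cycle in 21 of 41, with TOP2A at -0.36 ± 0.18 (SD, n = 4). DNA methylation and histone genes were positive in 16 of 34, with MAT2B at 0.37 ± 0.16, and AMPK, PPAR and mitochondrial biogenesis genes in 12 of 29, with ESRRA at 0.71 ± 0.70 (SD, n = 4).

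The last Holstein lists follow. Antioxidant genes were positive in 17 of 39, with KEAP1 at 0.65 ± 0.62 and GPX4 at -0.40 ± 0.47, and stress response genes in 15 of 38, with GADD45B at 0.98 ± 0.42 and asparagine synthetase ASNS at -0.78 ± 0.52 (SD, n = 4). Junction genes were positive in 12 of 29, with PKP2 at 0.32 ± 0.13, maternal oocyte transcripts in 8 of 17, with ZAR1L at -0.80 ± 0.90, and interferon response genes in 4 of 13, with IFIT5 at -1.39 ± 1.23 (SD, n = 4). Sperm markers were positive in 6 of 9, with TSSK6 at 0.13 ± 0.07, fatty acid uptake genes in 8 of 16, and ribosomal proteins in 32 of 64, with RPS12 at 0.45 ± 0.38 and RPS18 at -0.39 ± 0.42 (SD, n = 4). Median, mean and test differed in sign for the fatty acid uptake, oxidative phosphorylation, antioxidant, trophectoderm and histone lists.

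**Figure D2:**
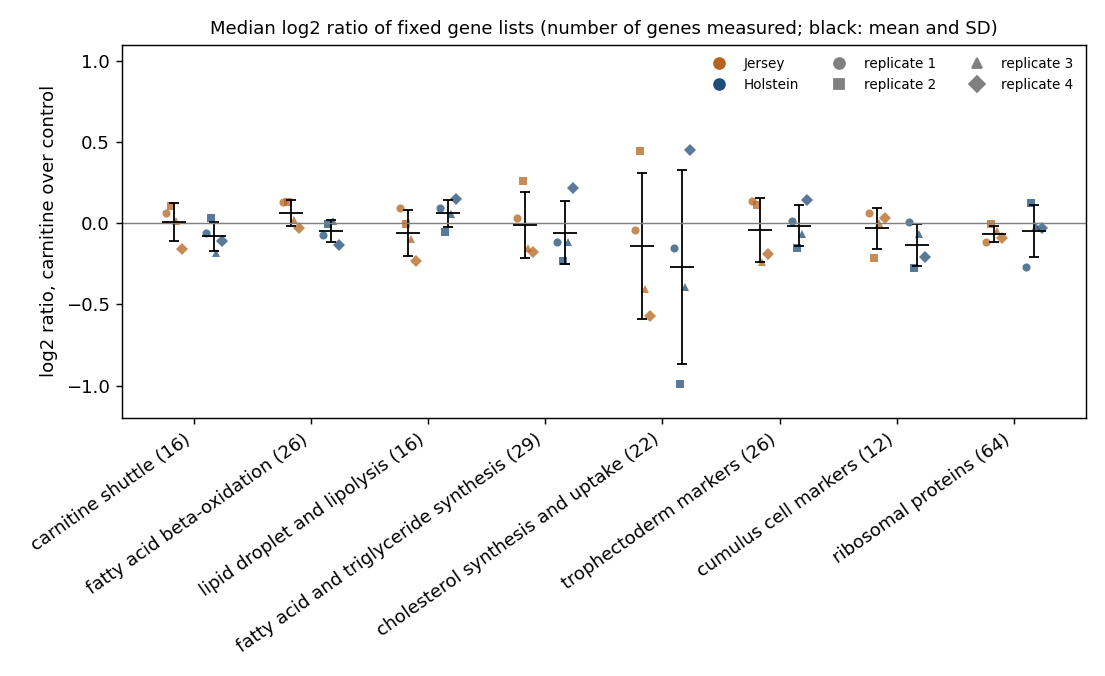
Median log2 ratio of carnitine over control (vertical axis) of 8 fixed gene lists, with the number of genes measured (horizontal axis), in Jersey (orange) and Holstein (blue). Symbols are replicates, and black bars are the mean and SD of 4 replicates. The cholesterol list spans from -0.99 to 0.45 in Holstein, a wider range than the other lists drawn.

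Over both breeds, the highest-ranked genes did not pass. PCMTD2 averaged 0.40 over both breeds, the zinc transporter SLC30A6 0.36 and the translation factor EIF1B 0.21, each higher with carnitine in 8 of 8 replicates. DAPL1 averaged -0.60, the ceramide synthase CERS5 -0.35 and CKS1B -0.25, each lower in 8 of 8. MRPS11 averaged -0.34 and NSD3 -0.23, each positive in 1 of 8 replicates, and UBE2G1 averaged 0.22 with 5 of 8 positive. Of these, UBE2G1 had -0.05 in Jersey, and NSD3 was above the negative-control limit there on 2 of 8 arrays in the carnitine channel and 3 of 8 in the control channel, so its Jersey ratio is near the floor. DHX34 had positive ratios in 8 of 8, but lay below the negative-control limit on all arrays of both Jersey groups. With limma 0 of 27303 probes passed, the smallest adjusted p was 0.9995, and 919 had an unadjusted p under 0.05 against 1365 by chance. The other PCMTD2 probes had 0.06 and 0.03 in Jersey and 0.01 and 0.21 in Holstein. Without Holstein replicate 3, limma called 1 probe, SEC61A1, with a log2 ratio of 0.77 over both breeds. This ratio comes from Holstein, as SEC61A1 had 0.02 ± 0.04 in Jersey (SD, n = 4). The same setting called it for the difference between breeds too, at -1.49, so no effect shared by the breeds is shown.

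The last comparison asks whether the breeds responded differently. A dye bias that differs between the Jersey slides stays in this difference, since each of them holds a single dye orientation, and cannot be told apart from a breed response. KLHL26 had 0.27 ± 0.15 in Jersey and -0.38 ± 0.09 in Holstein, TIMELESS 0.20 ± 0.12 and -0.40 ± 0.12, ZCCHC8, of nuclear RNA decay, 0.21 ± 0.12 and -0.31 ± 0.13, and the antigen presentation gene BOLA-DMB 0.37 ± 0.19 and -0.65 ± 0.35 (SD, n = 4). In the opposite sense, UBE2G1 had -0.05 ± 0.12 in Jersey and 0.48 ± 0.06 in Holstein, the selenoprotein SELENOH -0.29 ± 0.22 and 0.61 ± 0.27, SLC4A7 -0.34 ± 0.18 and 0.22 ± 0.09, and UNC13A, of vesicle release, -0.07 ± 0.06 and 0.25 ± 0.06 (SD, n = 4). The telomerase RNA TERC was above the negative-control limit on 7 of 8 Holstein arrays in the carnitine channel and on 0 of 8 in the control channel. In Jersey it was above the limit on 1 of 8 arrays in each channel, so its ratio there, -0.12 ± 0.05 (SD, n = 4), is near the floor. The lower bound on its mean ratio in Holstein was 1.28-fold, given without an error. Its adjusted p by limma for the difference between breeds was 0.955. NSD3 had -0.04 ± 0.05 in Jersey, where it was mostly below the limit, and -0.42 ± 0.05 in Holstein (SD, n = 4). UNC13A was above the limit on 3 and 2 of 8 arrays in Jersey and on 6 and 1 of 8 in Holstein, in the carnitine and the control channel, so its ratios are near the floor. None of these differences passed: with limma, 0 of 27303 probes did, the smallest adjusted p was 0.955, and 1373 had an unadjusted p under 0.05 against 1365 by chance. The other ZCCHC8 probes had 0.08 and 0.01 in Holstein.

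The difference between breeds passed for 0 of 24 lists by camera, where the smallest adjusted p was 0.382, for lipid droplet genes and for ribosomal proteins. The log2 ratio of carnitine over control was lower in Jersey than in Holstein for 11 of 16 lipid droplet genes, led by PLIN3, and for 41 of 64 ribosomal proteins, led by RPS10. This ratio was higher in Jersey for 16 of 22 cholesterol genes, 10 of 12 cumulus markers and 11 of 16 carnitine shuttle genes, and none of these lists passed. Without Holstein replicate 1 the ribosomal list was called, with an adjusted p of 4.55e-05 by limma's camera at the preset correlation and of 0.646 at an estimated one, while without Holstein replicate 2 its adjusted p was 0.978. Without Holstein replicate 4 the cholesterol list was called, with an adjusted p of 0.00520 at the preset correlation and of 0.730 at an estimated one. SLC27A4 was the 1 gene of all lists that passed for the difference when adjusted over the list alone, with 0.01 ± 0.19 in Jersey and 0.71 ± 0.23 in Holstein (SD, n = 4). Across the 27303 probes the effects of both breeds correlated with Pearson's r of -0.054 and Spearman's rho of -0.087. All 8 sign flips of the Holstein replicates gave an r as large in size, and 6 of 8 a rho as large, so the exact two-sided p was 1 and 0.75, where 0.125 is the smallest that 8 flips allow. Genes are not independent replicates here either. After scaling the log ratios between arrays, r was 0.197.

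**Figure D3:**
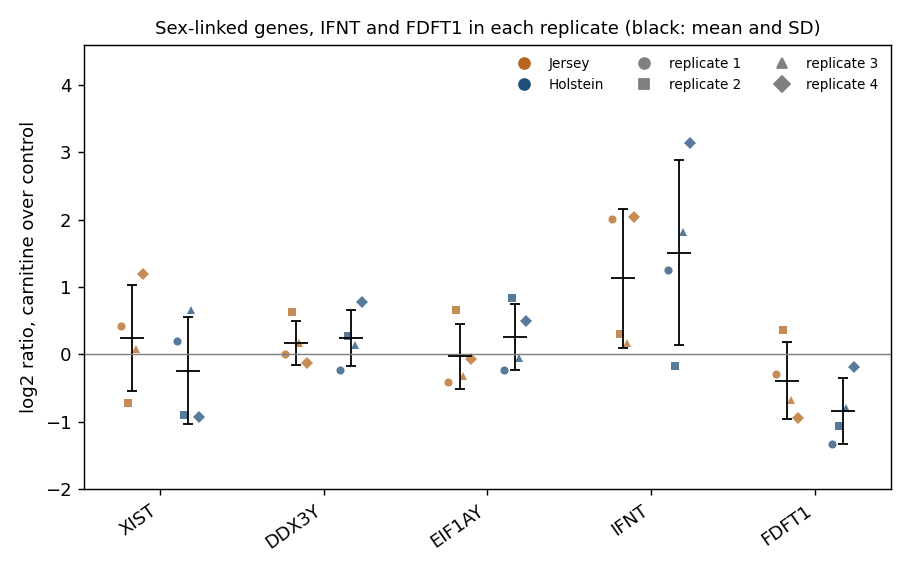
Log2 ratio of carnitine over control (vertical axis) for XIST, DDX3Y, EIF1AY, IFNT and FDFT1 (horizontal axis), in Jersey (orange) and Holstein (blue). Symbols are replicates, and black bars are the mean and SD of 4 replicates. XIST runs from -0.94 to 1.19, and IFNT lies above 0 in 7 of 8 replicates.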

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

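No test chosen after a result was seen is used in this part, except that HSPA1A was picked after its values were seen. Each result below has 1 of 4 replicates far from the other 3 by Dixon's test. This was so in 9 of 138 groups of 4 replicates examined, where chance gives about 6.9.

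HSPA1A, the inducible heat shock protein 70, had a log2 ratio of -3.50 in Jersey replicate 1, against -0.18 to 0.26 in the other Jersey replicates, and of -2.39 in Holstein replicate 2. TNRC6A had 0.79 in Jersey replicate 2, against 0.33 to 0.39. METTL26 had -0.17 in Jersey replicate 1, against -0.48 to -0.47. SETD3 had -0.13 in Jersey replicate 1, against 0.08 to 0.09, but was above the negative-control limit on 0 of 8 Jersey arrays in the carnitine channel and 1 of 8 in the control channel, so these ratios are near the floor. The median of the fatty acid uptake list had -0.13 in Jersey replicate 2, against 0.04 to 0.05. SEC61A1 had 0.34 in Holstein replicate 3, against 1.41 to 1.62, and is called by limma, with a log2 ratio of 1.51, when that replicate is left out. The carnitine importer SLC22A5 had 0.75 in Holstein replicate 4, against -0.24 to -0.21. The lipase PNPLA2 had 1.38 in the same replicate, against -0.31 to -0.05. The median of the nuclear oxidative phosphorylation list had -0.20 in Holstein replicate 1, against 0.01 to 0.05. No explanation was tested for any of these 9 results.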

How the results depend on the processing

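The added settings, chosen after seeing the data, are median foreground, a negative-control limit from median and MAD, the sex index as covariate, Holstein replicate 1 from a single array, each Holstein slide alone, and the Holstein slide as a fixed term with the replicate block. Every setting of background, normalization, filter and variance prior, and the deposited values, left the count of limma calls at 0 in Jersey, in Holstein, over both breeds and in the difference, as in the reported fit, where 763, 1579, 919 and 1373 probes had an unadjusted p under 0.05. So did an adjusted p under 0.1 and the added settings other than the last, where each Holstein slide alone was run for the Holstein effect only. Unadjusted p under 0.05 with at least 1.5-fold, a looser criterion, gave 70, 431, 57 and 459 probes. The stricter filter on dim probes left 7980 probes, and would leave 17271 without the Holstein array of replicate 3 with carnitine in Cy5, whose negative-control limit was 736 in Cy3. Named genes were compared in 1327 cases over 23 alternatives on replicate means: 1306 kept direction and side of the threshold, 1 was newly called, 20 changed sign with no call on either side and 0 reversed. In 7 fits to single arrays, 170 of 260 cases were kept and 90 were newly called: 31 with no replicate block, 49 with slide as a random block and 10 with slide as a fixed term and no replicate block.

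Leaving out 1 replicate at a time gave 0 calls in Jersey throughout. It gave 0 to 13 in Holstein, with 13 without replicate 3 and 1 without replicate 2, 0 to 1 over both breeds and 0 to 1 for the difference, each 1 without Holstein replicate 3. Lists called ranged from 1 to 2 in Jersey, from 0 to 2 in Holstein and from 0 to 1 for the difference, and each list called so had an adjusted p of 0.537 or more by limma's camera with an estimated correlation. The r between breeds ranged from -0.175 to 0.136, and was 0.197 after scaling between arrays. The cause was not tested.

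On pairing and blocks, all 16 arrays in one fit with the replicate as a block gave 2 calls and 2 lists in Holstein and 0 calls in the other comparisons, with a correlation of 0.779 within blocks. Adding slide as a fixed term in Holstein to this fit again gave 2 calls and 2 lists. Taken as independent, without a replicate block, the 16 arrays gave 16 calls in Jersey, 290 in Holstein, 25 over both breeds and 51 for the difference, since each dye-swap pair then counts as 2 samples. With slide as a random block there were 10103, 12379, 10544 and 12714 calls at a correlation of -0.276. A negative value means that arrays of one slide were less alike than arrays of different slides, over which each dye-swap pair is spread, so these counts are not read as effects of carnitine. Slide as a fixed term without a replicate block, where pairs again count as 2 samples, gave 59 calls in Holstein. Holstein arrays paired within slides gave 5 calls and 1 list. The cause was not tested.

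The Jersey list count of 1, ribosomal proteins, went to 0 with median centring in place of loess, with camera's estimated correlation and with fry. The Holstein list count of 0 went to 2 without background correction, with median centring, without a filter on dim probes and with the deposited values, each time cholesterol synthesis and cumulus markers. It went to 1, cholesterol synthesis, with the stricter filter and with the sex index as covariate. The cause was not tested.

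The breed difference in control embryos, 52 calls, was 0 in the carnitine channel, 91 without background correction and 0 to 16 without 1 replicate, with 0 without Jersey replicate 2 or Holstein replicate 1. With slide as a random block it was 15784, at a correlation of -0.267, which is negative and gives no usable count. The cause was not tested.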

Other observations

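Tests chosen or reworked after a result was seen are those on dye error and on the signs of X-linked genes in the first pattern, on co-moving members and on dye bias in the second, on sex and on trophectoderm in the third, and the counts of splits for calls of the carnitine comparisons and for Holstein and difference lists. The tests on sex first took the form of 25 correlations with the sex index over the 8 replicates. They were replaced by counts of signs, because the index falls into a group of 3 replicates at or below -1.36 and a group of 5 at or above 0.16. The count of probes that follow the sex index was also made after seeing the data, and fits a linear slope over these same groups. The criterion for trophectoderm was tightened to an adjusted p after its result was seen. The X-linked gene list was written from general knowledge after the data had been seen, leaving out genes noticed there.

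IFNT, the signal by which ruminant trophectoderm announces pregnancy, averaged 1.32 ± 1.14 (SD, n = 8) over the replicates of both breeds and was higher with carnitine in 7 of 8. The exact sign-flip p was 0.0234 for this gene alone over 8 replicates, and limma's adjusted p over all probes was 0.9995, so it did not pass. HMGCS1 and INSIG1, of the cholesterol pathway, averaged -0.75 ± 1.51 and -0.43 ± 0.70 (SD, n = 8), each lower in 6 of 8, with exact sign-flip p of 0.203 and 0.117. These genes are among 10 picked after their values were seen, of which IFNT alone had an exact p under 0.05, without adjustment for the 10.

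Control embryos of the breeds differed in 52 probes by limma, 4 higher and 48 lower in Jersey. TBC1D4, a regulator of glucose transporter traffic, was higher in Jersey by 1.81 on the log2 scale with an adjusted p of 0.0105, and RUNDC1 by 1.06 and KCTD11 by 1.73. METTL21A, with a difference of -1.93, and the kinesin KIF3B, with -0.95, were lower in Jersey. Only 1 of 35 splits of the 8 replicates gave as many calls, the real one, and the highest other gave 1. A share of 1 of 35 is the smallest that these splits allow, so chance is made less likely but is not excluded. Every slide held a single breed, so breed and slide cannot be told apart, and the count was 0 in the carnitine channel and 0 without Jersey replicate 2 or Holstein replicate 1.

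The first pattern is that replicates of a breed move apart. Dye or array error is argued against by the arrays of each pair, whose lowest r was 0.699. An unequal share of male and female embryos in the carnitine and control pools may contribute. The median of 85 X-linked genes other than XIST had the sign of the sex index in 8 of 8 replicates (exact two-sided sign p = 0.00781, the smallest that 8 replicates allow), and lay beyond all 10000 brightness-matched random lists in 7 of 8. As the whole cause this imbalance is argued against only as far as the index measures it. Fitting the index lowered the mean variance between replicates by 28.3%, against at most 19.7% in 100 shuffles of the index. The index rests on XIST, DDX3Y and EIF1AY alone, and noise in these genes would lessen the fall.

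The probes that followed the sex index numbered 697 by limma, 521 higher and 176 lower where the index was higher. XIST, a part of the index, is one of them by construction. Others were the X-linked VBP1, with a slope of 0.78 per log2 unit of the index and an adjusted p of 0.0116, and HPRT1, with a slope of 0.83. Genes outside the X-linked list followed it as well, such as BUB1, with a slope of -0.59 and an adjusted p of 0.0116 by limma. That list is partial, so how many of the 697 probes are X-linked was not counted.

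The second pattern is the lower ribosomal protein list in Jersey. Brightness alone, after loess, did not give such a shift: 0 of 10000 brightness-matched lists had as low a mean as -0.10. These lists hold unrelated genes, and loess had already removed trends with brightness. With median centring in place of loess the call was lost, with an adjusted p of 0.780 by limma's camera. A part of brightness-dependent normalization is therefore not settled. Members that move together by chance could account for it, as the p with an estimated correlation was 0.141. A dye bias alike on both slides is argued against by the design alone, since it cancels in the mean of a dye-swap pair. The list's median in these means averaged -0.066 ± 0.050 (SD, n = 4), which restates the pattern and adds no evidence of its own. A dye bias of different size on the 2 slides would not cancel, and cannot be told apart from carnitine in Jersey, where each slide holds 1 dye orientation. The list's median lay 0.11 above its Jersey mean over arrays with carnitine in Cy5, and as far below it with control in Cy5. An effect of carnitine stays open as untested.

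The third pattern is the swing of cholesterol synthesis genes between replicates. Dye or array error is argued against, since both arrays of a pair gave the list's median one sign in 8 of 8 pairs. A sex imbalance cannot be told apart from other causes: the median had the sign opposite to the sex index in 7 of 8 replicates, Holstein replicate 2 being the exception. An unequal share of trophectoderm may contribute, with r = 0.828 and rho = 0.881 to the trophectoderm markers' median (exact permutation p = 0.0116 and 0.00724, adjusted 0.0886 and 0.0555 over 23 relations, r = 0.696 without the 2 replicates farthest from the median and 0.853 centred by breed), so the adjusted p leaves it open. The inner cell mass markers' median leaned the same way, with r = 0.667 and rho = 0.667 (adjusted exact permutation p = 0.258 and 0.273). The relation is therefore not shown to be particular to trophectoderm. The list's median also followed triglyceride synthesis (r = 0.949, rho = 0.976, adjusted exact permutation p = 0.000856 and 0.00456, r = 0.873 without those 2 replicates and 0.948 centred by breed) and, as closely, the antioxidant list (r = 0.913, rho = 0.976, adjusted exact permutation p = 0.000856 and 0.00456, r = 0.983 without those 2 replicates and 0.913 centred by breed), so the relation is not specific to lipid synthesis.

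Other sign choices or splits of the replicates were counted for each result of the carnitine comparisons. With 4 replicates a breed has 8 sign choices, too few for a share under 0.05. In Jersey 8 of 8 gave as many calls as the real 0, the highest other being 0, 7 of 8 as many probes at unadjusted p under 0.05 as the real 763, the highest other being 1505, and 3 of 8 as many lists as the real 1, the highest other being 2. In Holstein these were 8 of 8 for the real 0 calls (highest other 2), 4 of 8 for the real 1579 probes (highest other 2404) and 8 of 8 for the real 0 lists (highest other 4). Over both breeds, 100 of 100 sign choices drawn gave as many calls as the real 0 (highest other 82) and 80 of 100 as many probes as the real 919 (highest other 3574). For the difference, 35 of 35 splits gave as many calls as the real 0 (highest other 163), 12 of 35 as many probes as the real 1373 (highest other 3373), and 35 of 35 as many lists as the real 0 (highest other 4). Where the real count is 0 every sign choice or split reaches it, so those counts say nothing about chance. For the probes at unadjusted p under 0.05 over both breeds and in the difference, chance is not excluded. Some sign choices and splits called many more probes than the real one, up to 82 over both breeds and 163 for the difference. A structure of the replicates other than treatment and breed could give this, which was not tested.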
